A study of Zea mays with 2 samples.

How the data were processed

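Total RNA was taken from 1 cm segments of the base and the tip of the third leaf of Mo17 seedlings 9 days old, per the labels' protocols. The plants grew at 500 micromoles of light per square metre and second with 12 hours of light at 31 degrees and 12 hours of dark at 22 degrees. Per the labels, mRNA was selected on oligo(dT) beads, 100 ng was used for each library, and cDNA was primed with random hexamers in a kit that does not mark the strand. Each position has 1 library. Nothing in the labels says how many plants were pooled for it.

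The authors deposited, for each library, a count of how many times each distinct read sequence was sequenced, without normalization. They also deposited the genome positions of those sequences, aligned over their first 32 bases with at most 2 mismatches, per the file that describes the columns. The aligner and the genome build are not given in the sources used here, and neither is any rule on how many positions a read may have; at most 15 are listed. All chromosome positions are printed as deposited. Reads were 36 bases long in the base library, while 74.7% of the tip library's reads were 35 bases long and the rest 36. The labels do not say why.

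The design fixed before the data were examined assigned reads to annotated genes, by position or by matching transcripts. This could not be run, because no genome, transcripts or annotation in the coordinates of the deposited alignments was used here, and the gene table at hand is of another assembly without sequences. It was replaced, after the file formats were seen and before any read was counted, by 2 measures. Results that the fixed design words as genes are therefore given for transcribed regions or for proteins.

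First, reads were matched to a panel of 81 protein sequences with a total of 19781 residues. These sequences were written down from general knowledge of plant proteins. They do not come from the deposited files or from a database, and errors in them lose reads. Each was divided into overlapping windows of 11 residues, a read was translated in 6 frames over its first 35 bases, and it was counted for a protein if a frame equalled a window of that protein alone. Such a count covers all genes that encode the window, so it is a value for a protein family and not for 1 gene. A protein was kept if at least 20 of its windows and at least 30% of them were found and it had at least 100 reads in both libraries together; 77 proteins passed. The limits on windows were set before any read was counted. Plastocyanin, a KNOX homeodomain, dehydrin DHN1 and alpha-zein did not. As a check, the same windows read backwards matched 13 reads in the base library and 12 in the tip library, against 1616486 and 2901786 for the true windows. All reads were searched, aligned or not, so the protein counts and their rpm include reads without a position. Shares of aligned reads in the results count only the aligned ones, a choice made after seeing the data.

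Second, reads with 1 deposited position were joined into transcribed regions wherever the gap between them was at most 50 bp, pooling both libraries. A region was linked to a protein if it held at least 5 distinct windows of it. Regions with at least 100 reads were compared.

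Values in rpm are reads scaled to the total of reads with at least 1 deposited position, of which the base library had 33054790 and the tip library 32681849. A library at 0 was set to 3 reads. Intervals are exact 95% Poisson, binomial or conditional binomial intervals. They cover counting error only, since copies made by PCR are not independent molecules. With 1 library per position there is no test, and a fixed size rule of 4-fold replaced it. The median of a list is given with the exact order-statistic interval, or the range where fewer than 6 proteins were measured or the interval spans it. A list's median over regions was placed among 10000 random lists of as many regions, matched on mean expression in 20 bins.

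Before the data were examined 29 gene lists were fixed. Panel proteins represent 22 of them, and 21 have a protein that passed, many with only 1 or 2. The 7 lists without a panel protein (plastid ribosomal proteins, auxin response, gibberellin and brassinosteroid metabolism, benzoxazinoid synthesis, senescence and protein breakdown, pollen proteins and root proteins) were not analysed here. Another 7 groups of panel proteins were added with the panel. The rule for naming genes took the 10 largest folds with product names in each direction, the 5 genes with most reads in each library and the 4 members of each list with most reads. Without gene names only the last part could be followed, applied to panel proteins. Other proteins, regions and family members that the text names were chosen after their values were seen.

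Alternatives fixed beforehand were median-of-ratios scaling, the trimmed mean of M-values, totals without the 20 regions of each library with most reads, distinct sequences counted once, shared reads, 0 mismatches, other minimums, thinning and interval bounds. Others were added after seeing the data, such as 35-base or 36-base tip reads alone. A transcript can give only a limited number of distinct sequences. Counting each once can therefore shrink the ratio of an abundant transcript with or without PCR copies. The trimmed mean of M-values was computed with edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and a C program for the search of reads.

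The steps were tested on simulated data. The search found 500 of 500 simulated reads with known windows and matched 0 of 4500 random reads. In simulated counts for the 46949 regions of the tip against base comparison, 100 of 100 regions changed 8-fold and 0 of 100 changed 2-fold passed the 4-fold rule. None of the unchanged regions did, and the 95% interval held the true ratio in 95.6% of them and in 93% of the changed ones. The simulated counts held counting error alone. They check the calculation and say nothing about the spread between libraries.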

Results

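The deposited data compare 2 mRNA sequencing libraries of the maize inbred line Mo17. One was made from a 1 cm segment at the base of the third leaf of 9-day-old seedlings, and the other from a 1 cm segment at the tip of that leaf. In a grass leaf the cells are laid down at the base, so the base holds young cells and the tip holds the oldest cells. The series describes its purpose as comparing RNA from different segments of a developing leaf. Each position is represented by 1 library, so no test of the difference between positions was possible and no value below has a replicate check. Intervals are 95% intervals for counting error only. The base library held 48051456 reads in 24205975 distinct sequences, and the tip library held 46519038 reads in 20519068 distinct sequences.

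Transcripts of photosynthesis were higher in the tip library, and transcripts of histones, ribosomal proteins and tubulins were higher in the base library. The files give read sequences and genome positions but no gene names, so transcripts were counted by the protein they encode. Of 77 proteins or protein families measured, 22 were at least 4-fold higher in the tip library and 34 were at least 4-fold higher in the base library, on the scale of rpm (reads scaled to the library's aligned reads). The median of 46949 transcribed regions was itself lower in the tip library, at a log2 ratio (tip over base) of -0.98. Relative to that median, 24 proteins were at least 4-fold higher in the tip library and 29 in the base library. Ratios relative to it are given for lists and for proteins whose 4-fold call or direction they change.

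**Figure D1:**
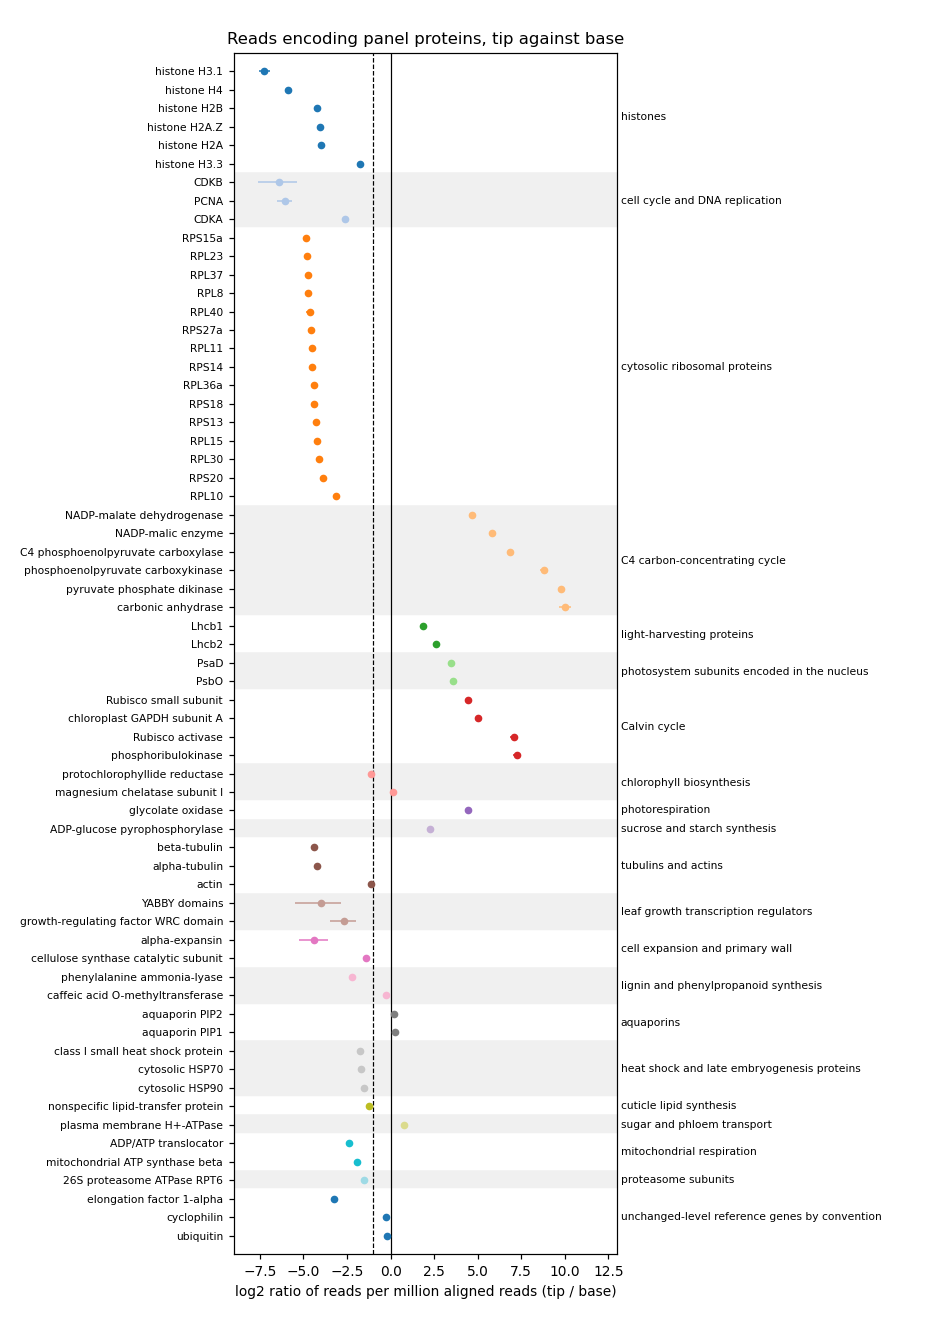
The horizontal axis is the log2 ratio of rpm (tip over base) and each point is a protein or protein family of the lists fixed beforehand, with its 95% counting interval. The solid line marks equal levels and the dashed line the median of all transcribed regions (-0.98); ubiquitin, cyclophilin and caffeic acid O-methyltransferase lie below 0 but above the dashed line, so their direction turns under scaling to that median.

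Enzymes of the C4 cycle, which concentrates carbon dioxide around Rubisco in maize leaves, were higher in the tip library for 6 of 6 proteins measured. Their median log2 ratio was 7.83 (range of the 6 proteins 4.70 to 10.01), or 8.81 relative to the median region. Their aligned reads made up 0.0240% of all aligned reads in the base library and 3.46% in the tip library. Pyruvate phosphate dikinase, which regenerates the carbon acceptor, rose from 19.0 to 16658 rpm, 878-fold (812 to 951). C4 phosphoenolpyruvate carboxylase, which makes the first fixation, went from 112 to 12979 rpm, 116-fold (112 to 119). NADP-malic enzyme, which releases carbon dioxide in the bundle sheath, was 56.0-fold higher in the tip library (54.2 to 57.8). Carbonic anhydrase, which supplies bicarbonate to the carboxylase, was represented by 80 reads in the base library and 81375 reads in the tip library, 1029-fold higher (827 to 1298). Of the remaining members, phosphoenolpyruvate carboxykinase was 445-fold higher (379 to 527) and NADP-malate dehydrogenase 25.9-fold higher (24.6 to 27.3). The folds were smaller with distinct sequences counted once: the log2 ratio of the dikinase went from 9.78 to 6.46, of the carboxylase from 6.85 to 4.08, of NADP-malic enzyme from 5.81 to 3.69 and of carbonic anhydrase from 10.01 to 7.09. That setting, here and below, can shrink ratios of abundant transcripts by itself, since a transcript gives a limited number of distinct sequences.

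These enzymes belong to families, and in some of these the regions differed in direction, as shown here by regions chosen after their values were seen. A gene can be split into several regions at gaps of more than 50 bp. Counts of regions, here and below, are therefore not counts of genes or family members. The genomic region with most windows of C4 phosphoenolpyruvate carboxylase lay on chromosome 9 from 59746061 to 59750235, in the coordinates of the deposited alignments, whose genome build is not given in the sources used here. It held 2311 reads in the base library and 420134 reads in the tip library, at a log2 ratio of 7.52 (7.46 to 7.58). A region on chromosome 7 from 75486059 to 75487304, which encodes 48 of the same windows, held 1107 and 404 reads, at a log2 ratio of -1.44 (-1.61 to -1.27). Of 20 regions with phosphoenolpyruvate carboxylase windows, 6 were at least 4-fold higher in the tip library and 7 in the base library. Of 17 regions with NADP-malic enzyme windows, 8 were at least 4-fold higher in the tip library and 6 in the base library. In the other 4 families all regions were at least 4-fold higher in the tip library, among them 22 encoding pyruvate phosphate dikinase and 6 encoding NADP-malate dehydrogenase. The main carbonic anhydrase region, on chromosome 3 from 213888885 to 213892470, held 10 and 100302 reads.

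Calvin cycle enzymes, which turn fixed carbon into sugar phosphates, were also higher in the tip library for 4 of 4 proteins measured. Their median log2 ratio was 6.04 (range of the 4 proteins 4.43 to 7.23), or 7.03 relative to the median region, and their aligned reads made up 0.0224% of all aligned reads in the base library and 0.697% in the tip library. Rubisco small subunit was 21.6-fold higher in the tip library (21.0 to 22.2) and chloroplast GAPDH subunit A was 32.4-fold higher (31.1 to 33.8). Phosphoribulokinase, which makes the carbon acceptor of Rubisco, was 150-fold higher (132 to 172). Rubisco activase, which keeps Rubisco active, was 134-fold higher (115 to 157). With distinct sequences counted once the log2 ratios were 2.85 for the small subunit, 3.13 for GAPDH subunit A, 4.89 for phosphoribulokinase and 4.77 for Rubisco activase.

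Nuclear-encoded proteins of the light reactions were also higher in the tip library. Light-harvesting proteins Lhcb1 and Lhcb2, which bind chlorophyll in the antenna of photosystem II, were 3.69-fold (3.65 to 3.73) and 6.13-fold (6.02 to 6.23) higher in the tip library. Lhcb1 passed 4-fold relative to the median region, at a log2 ratio of 2.87. Lhcb2 did not reach 4-fold with distinct sequences counted once, at a log2 ratio of 1.86. In the base library Lhcb1 was already at 1267 rpm, against 19.0 for pyruvate phosphate dikinase. PsaD of photosystem I was 10.9-fold higher in the tip library (10.6 to 11.3), and PsbO of the oxygen-evolving complex was 12.1-fold higher (11.7 to 12.5). Counting distinct sequences once, their log2 ratios went from 3.45 to 2.30 and from 3.59 to 2.32. In photorespiration, glycolate oxidase was 21.8-fold higher in the tip library (19.0 to 25.2) as a family, while 1 of its 3 regions was at least 4-fold higher in the tip library and 2 in the base library. ADP-glucose pyrophosphorylase, which commits carbon to starch, was 4.85-fold higher (4.45 to 5.30), but below 4-fold with windows of 1 substitution also counted (log2 ratio 1.77) or with distinct sequences counted once (1.49). Of its 4 regions, 2 were at least 4-fold higher in the tip library and 1 in the base library.

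Counted by panel windows, neither chlorophyll synthesis enzyme measured was 4-fold different between the libraries, but for protochlorophyllide reductase the regions did not bear this out. Magnesium chelatase subunit I had 87.7 rpm in the base library and 98.0 in the tip library, a log2 ratio of 0.16. Protochlorophyllide reductase had 211 and 97.1 rpm, a log2 ratio of -1.12 (-0.14 relative to the median region). A pair of its regions, chosen after their values were seen, differed. One, on chromosome 2 from 1448810 to 1450379, held 36306 reads in the base library and 148 in the tip library. The other, on chromosome 5 from 24724302 to 24727414, held 5925 and 5848 reads. The window count of this protein was 6983 and 3174 reads, with 161 of 304 windows found. It misses many reads of these regions. The reads of the pair together lay further toward the base library than the window count. The window ratio should therefore not be taken as a value for the whole family.

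**Figure D2:**
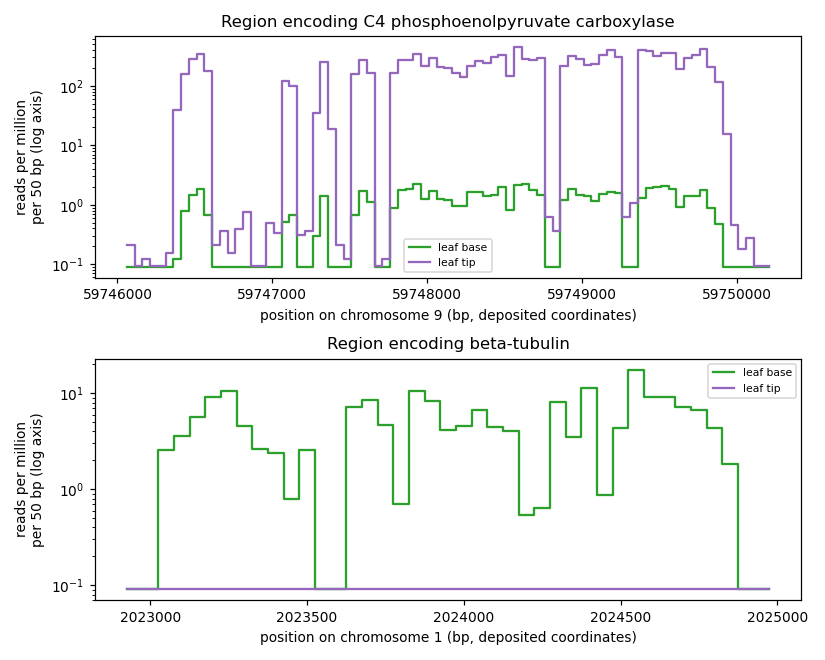
Reads scaled to the library's aligned reads (rpm) in bins of 50 bp (log axis, bins with fewer than 3 reads drawn at 3 reads) along the region with most windows of C4 phosphoenolpyruvate carboxylase (top) and of beta-tubulin (bottom), with the base library in green and the tip library in purple. The tip library was higher in 80 of the 84 bins of the first region and in 0 of the 42 bins of the second. The first region has the highest log2 ratio (7.52) of the 20 regions with its windows, which range down to -6.96. The 39 beta-tubulin regions range from -8.93 to 1.15, so neither profile stands for its family.

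Histones, which package DNA, were higher in the base library: 5 of 6 proteins were at least 4-fold higher there and histone H3.3 was 3.36-fold higher. The median log2 ratio was -4.14 (range of the 6 proteins -7.24 to -1.75), or -3.16 relative to the median region. Histone H4 fell from 3151 to 52.3 rpm, 60.3-fold lower in the tip library (57.5 to 63.3). Histone H2B was 18.8-fold lower (18.2 to 19.5), histone H2A 16.1-fold lower (15.2 to 17.1) and histone H3.1 151-fold lower (123 to 187). Histone H2A.Z, a replacement histone, was 16.5-fold lower (14.6 to 18.7), close to histone H2A. Distinct sequences counted once gave log2 ratios of -3.59 for H4, -2.03 for H2B, -2.32 for H2A and -5.31 for histone H3.1. Aligned histone reads made up 0.591% of all aligned reads in the base library and 0.0221% in the tip library. The 19 regions encoding histone H4 were all at least 4-fold higher in the base library.

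Cell cycle and DNA replication proteins were at least 4-fold higher in the base library for 3 of 3 proteins, 2 of them relative to the median region. PCNA, the sliding clamp of DNA polymerases, was 67.4-fold higher in the base library (51.3 to 90.4). The mitotic kinase CDKB was 83.4-fold higher (42.1 to 194), with 675 reads in the base library and 8 in the tip library. That ratio rests on exact windows: its log2 ratio was -6.38, and -3.48 with windows of 1 substitution also counted. PCNA went from -6.07 to -4.47 with distinct sequences counted once. The kinase CDKA, which is not restricted to mitosis, was 6.05-fold higher (5.42 to 6.77), a log2 ratio of -1.61 relative to the median region and -1.87 with distinct sequences counted once. The median log2 ratio of the 3 proteins was -6.07, or -5.09 relative to the median region.

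Cytosolic ribosomal proteins were at least 4-fold higher in the base library for 15 of 15 proteins, on the scale of aligned reads and relative to the median region. Their median log2 ratio was -4.49 (95% interval of the median -4.74 to -4.22), or -3.51 relative to the median region. RPL23 was 27.3-fold higher in the base library (25.9 to 28.8), RPL8 26.7-fold (25.1 to 28.4), RPS14 22.5-fold and RPL10 8.67-fold (8.30 to 9.06). With distinct sequences counted once, the log2 ratios of RPL23, RPL8 and RPS14 were -2.34, -2.69 and -2.10, and 10 of the 15 passed 4-fold, RPL10 not among them. Their aligned reads made up 0.597% of all aligned reads in the base library and 0.0308% in the tip library. All 81 regions that encode them were at least 4-fold higher in the base library. With the 36-base reads of the tip library alone the median log2 ratio was -3.73, and with its 35-base reads alone it was -4.89.

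Tubulins, the subunits of microtubules, were higher in the base library, and actin differed less. Alpha-tubulin was 18.9-fold higher in the base library (18.5 to 19.3) and beta-tubulin was 20.9-fold higher (20.2 to 21.5). Counted by distinct sequences their log2 ratios were closer to the 4-fold limit, going from -4.24 to -2.08 and from -4.38 to -2.59. Actin was 2.21-fold higher (2.19 to 2.24), which is a log2 ratio of -0.16 relative to the median region. Of 19 regions encoding alpha-tubulin, 16 were at least 4-fold higher in the base library and 2 in the tip library. Of 39 regions encoding beta-tubulin, 36 were at least 4-fold higher in the base library and 0 in the tip library. Of 29 regions encoding actin, 17 were at least 4-fold higher in the base library and 3 in the tip library. The median log2 ratio of these 3 was -4.24, or -3.26 relative to the median region.

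Among regulators of leaf growth, the YABBY domains were represented by 98 reads in the base library and 6 in the tip library, 16.1-fold higher in the base library (7.16 to 45.1). The WRC domain of growth-regulating factors had 124 and 19 reads, 6.45-fold higher in the base library (3.96 to 11.1). It did not reach 4-fold relative to the median region (log2 ratio -1.71) or with 36-base tip reads alone (-1.81), and its 2 regions had log2 ratios of -1.27 and -0.67. In wall expansion, alpha-expansin, which loosens growing walls, was 20.6-fold higher in the base library (12.1 to 38.2), with 292 and 14 reads. Its log2 ratio went from -4.37 to -3.21 with 36-base tip reads alone, and both of its regions were at least 4-fold higher in the base library. The cellulose synthase catalytic subunit was 2.61-fold higher (2.42 to 2.82). In phenylpropanoid synthesis, phenylalanine ammonia-lyase was 4.58-fold higher in the base library (4.22 to 4.96), a log2 ratio of -1.21 relative to the median region and -0.94 with distinct sequences counted once. Caffeic acid O-methyltransferase had a log2 ratio of -0.26, which turned to 0.72 relative to the median region.

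Heat shock proteins were between 2.85-fold and 3.38-fold higher in the base library for 3 of 3 proteins, short of the 4-fold size rule. Their median log2 ratio was -1.70, or -0.71 relative to the median region. Cytosolic HSP70, a chaperone, had 3484 rpm in the base library and 1075 in the tip library. Its regions were at least 4-fold higher in the base library for 9 of 18 and in the tip library for 2. For cytosolic HSP90 these numbers were 5 and 0 of 12. Class I small heat shock protein, at 3.38-fold, had 31 of 78 windows found, and its 2 regions had log2 ratios of -0.05 and 0.85. The ADP/ATP translocator of mitochondria was 5.22-fold higher in the base library (5.08 to 5.36), a log2 ratio of -1.40 relative to the median region and -0.73 with distinct sequences counted once, and mitochondrial ATP synthase beta was 3.80-fold higher (3.70 to 3.90). The proteasome ATPase RPT6 was 2.93-fold higher, and nonspecific lipid-transfer protein was 2.39-fold higher (2.26 to 2.54). The plasma membrane H+-ATPase, which drives sugar uptake, had a log2 ratio of 0.78.

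The aquaporin families PIP1 and PIP2, water channels of the plasma membrane, had log2 ratios of 0.24 and 0.17 as families. Their regions spread from -1.27 to 8.92 for PIP1 and from -9.84 to 6.53 for PIP2. A PIP1 region on chromosome 4 from 169066278 to 169067132 held 13 reads in the base library and 6215 in the tip library.

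Genes that are used by convention as level references differed from one another. Elongation factor 1-alpha was 9.63-fold higher in the base library (9.48 to 9.78), but below 4-fold with distinct sequences counted once, where its log2 ratio went from -3.27 to -1.11. Ubiquitin and cyclophilin had log2 ratios of -0.20 and -0.29, which turned to 0.79 and 0.69 relative to the median region. The ubiquitin count can include reads from the ubiquitin part of RPS27a and RPL40 transcripts, which are made as ubiquitin fusions. By their own windows these ribosomal proteins had log2 ratios of -4.59 and -4.63. Ubiquitin values can therefore mix reference and ribosomal protein transcripts, in shares that were not measured. Of 15 regions with ubiquitin windows, 9 were at least 4-fold higher in the base library and 0 in the tip library. For cyclophilin these numbers were 1 and 0 of 6 regions. The median of the 3 reference proteins was -0.29, and it turned to 0.69 relative to the median region and to 0.66 with a median-of-ratios scaling. No read encoded a window of alpha-zein, a seed protein listed as a marker of a tissue not sampled. The upper end of its 95% interval was 0.112 rpm in the base library and 0.113 rpm in the tip library.

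Across the genome, 293672 transcribed regions were formed from reads with 1 deposited position, and 46949 of them held at least 100 reads in both libraries together. Of these, 5793 (12.3%) were at least 4-fold higher in the tip library and 15458 (32.9%) in the base library. With a median-of-ratios scaling these counts were 9075 and 10259, so the tip library's share of the 4-fold regions moved from 27.3% to 46.9%. With the 36-base tip reads alone, 3357 regions were at least 4-fold higher in the tip library and 15169 in the base library. With the 35-base tip reads alone these counts were 5278 and 15443. Only 11758100 of the 46519038 tip reads had 36 bases, so regions high in the tip library can fall short of 100 reads. The fall to 3357 can therefore not be read as an effect of read length. At least 10 reads were found in 95533 regions in the base library and in 73825 regions in the tip library, and in 63514 regions in both. A region is a stretch of aligned reads with a median length of 473 bp, and not a gene.

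**Figure D3:**
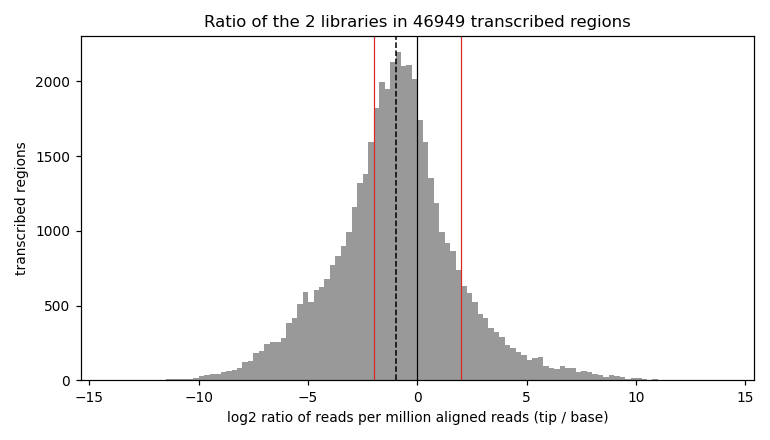
Histogram of the log2 ratio of rpm (tip over base) over 46949 transcribed regions with at least 100 reads. The dashed line is the median (-0.98) and the red lines are the 4-fold limits, with 5793 regions above the upper and 15458 below the lower limit.

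Reads were concentrated in fewer regions in the tip library. The 20 regions with most reads held 13.3% of the single-position reads of the tip library and 4.52% of those of the base library. The region with most reads in the tip library was the C4 phosphoenolpyruvate carboxylase region on chromosome 9. The region with most reads in the base library lay on chromosome 9 from 117891202 to 117892989, and it encodes 38 windows of sucrose synthase, which splits sucrose. It held 152003 reads in the base library and 166 in the tip library. Among regions that encode none of the proteins counted, a region with one of the highest ratios lay on chromosome 8 from 155786637 to 155787833, with 1 read in the base library and 104519 reads in the tip library, a log2 ratio of 16.69 (14.21 to 21.99). A region with one of the lowest ratios lay on chromosome 1 from 118067639 to 118070236, with 7731 reads in the base library and 1 in the tip library, a log2 ratio of -12.90 (-18.20 to -10.42).

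Among the fixed lists with at least 3 measured proteins, medians over their regions were set against 10000 random region lists matched on mean expression. Histones (-6.19), cell cycle and DNA replication (-4.75), cytosolic ribosomal proteins (-4.38) and tubulins and actins (-3.68) lay below the central 95% of the random medians. The C4 cycle (6.26) and the Calvin cycle (4.47) lay above it, as did the plastid-encoded proteins (4.39), a group added later with 6 regions. The reference genes had a region median of -3.35, below it, and 33 of their 46 regions were at least 4-fold higher in the base library. Elongation factor 1-alpha alone accounted for 25 of these regions and 23 of the 4-fold ones. Regions with ubiquitin windows can include those of the RPS27a and RPL40 fusions. Over the proteins the median of the list was -0.29. Heat shock regions had a median of -1.34, at percentile 11.7. The 6 regions of the plastid-encoded group came from PsbD, PsbB and Rubisco large subunit only. Reads with 1 position were 23.3%, 6.29% and 0.0702% of the tip library's window reads of these proteins. The placement of that group thus covers a small part of its reads. Several regions of a list can come from 1 gene, whereas the random regions were drawn from all compared regions. These percentiles describe the 2 libraries and are not a test.

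Reads with 1 deposited position made up 49.2% of the base library and 51.4% of the tip library. Reads with several positions made up 19.6% and 18.8%, and reads with none 31.2% and 29.7%.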

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

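With 1 library per position, no library could be compared with others of its group. What stands out are shares of reads within each library. Reads holding the sequencing adapter made up 7.42% of the base library and 6.46% of the tip library. Reads with at least 30 bases alike made up 0.868% of the base library and 0.0561% of the tip library. Among reads that encode a panel protein, 10.04% in the base library and 11.5% in the tip library had no deposited genome position. These last reads enter the protein counts but not the transcribed regions.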

How the results depend on the processing

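No paired analysis was possible because each position has 1 library. The alternatives with 35-base or 36-base tip reads alone, joins over 200 bp, bins of 1 kb, total reads as the scale, windows with 1 substitution, no gate on windows and aligned panel reads alone were chosen after seeing the data. The planned 3' end and organelle alternatives were not run, for want of transcripts and of organelle sequence names. In the alternatives run, the medians of the C4 cycle (5.05 to 8.77) and Calvin cycle (3.95 to 6.99) stayed above 0, and those of histones (-4.31 to -2.37), cell cycle proteins (-6.26 to -3.48), tubulins and actins (-4.29 to -2.08), ribosomal proteins (-4.89 to -2.10) and heat shock proteins (-1.91 to -0.23) below it. The median of the reference genes reversed, to 0.66 with the median of ratios, 0.60 with the trimmed mean of M-values and 0.22 with distinct sequences counted once. It was -0.19 without the 20 regions of each library with most reads and -0.0215 with 36-base tip reads alone, where cyclophilin alone turned to 0.23. The cause of the changes in this part was not tested.

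The 4-fold regions in the tip library numbered 9075 with the median of ratios (base library 10259), 8833 with the trimmed mean of M-values, 3357 with 36-base tip reads alone and 3561 with joins over 200 bp. Tip reads of 36 bases alone and joins over 200 bp can also change how many regions reach the minimum of 100 reads. In the base library the 4-fold regions numbered 9841 with distinct sequences counted once. At a minimum of 20 reads they numbered 9911 in the tip and 31575 in the base library, at 500 reads 2652 and 4762, and at 1 read 14920 and 39517. Detected regions numbered 229493 in the base and 210106 in the tip library at 1 read, 33377 and 21641 at 100 reads, and 53547 and 44553 with joins over 200 bp. The ribosomal median was -3.55 with the median of ratios, -3.60 with the trimmed mean of M-values, -2.10 with distinct sequences counted once, -3.73 with 36-base and -4.89 with 35-base tip reads. The heat shock median was -0.75, -0.81 and -0.23 under the first 3 of these, -1.91 with 36-base tip reads and -1.79 with 1 substitution allowed. The Calvin cycle median was 3.95 with distinct sequences counted once. In that setting the 4-fold calls of CDKA, RPS20, RPL10, RPL30, RPL36a, RPS27a, Lhcb2, ADP-glucose pyrophosphorylase, phenylalanine ammonia-lyase, the ADP/ATP translocator, eIF4A and the elongation factors 1-alpha and 2 ended. The limited number of distinct sequences per transcript and PCR copies cannot be told apart as reasons for these losses.

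Counting distinct sequences once, reads with 1, several and no positions made up 55.3%, 18.1% and 26.7% of the base library and 57.0%, 17.1% and 25.9% of the tip library. The reads of the lists, aligned or not, equalled percentages of the aligned total of the base and tip libraries that were 0.631% and 0.0239% for histones, 0.0196% and 0.00132% for cell cycle proteins, 0.762% and 0.0375% for ribosomal proteins, 0.0296% and 4.16% for C4 cycle enzymes, 0.0239% and 0.741% for Calvin cycle enzymes, 0.934% and 0.141% for tubulins and actins, 0.426% and 0.135% for heat shock proteins and 0.785% and 0.280% for reference genes in the setting of the ratios. With distinct sequences counted once they were 0.212% and 0.0322% for histones, 0.0164% and 0.00224% for cell cycle proteins, 0.250% and 0.0568% for ribosomal proteins, 0.0322% and 0.777% for C4 cycle enzymes, 0.0152% and 0.159% for Calvin cycle enzymes, 0.357% and 0.133% for tubulins and actins, 0.151% and 0.115% for heat shock proteins and 0.220% and 0.177% for reference genes. With 0 mismatches they were 0.694% and 0.0255% for histones, 0.0220% and 0.00131% for cell cycle proteins, 0.671% and 0.0353% for ribosomal proteins, 0.0278% and 3.80% for C4 cycle enzymes, 0.0286% and 0.858% for Calvin cycle enzymes, 0.988% and 0.158% for tubulins and actins, 0.422% and 0.130% for heat shock proteins and 0.943% and 0.345% for reference genes. With shared windows they were 0.835% and 0.0376% for histones and 0.0263% and 0.746% for Calvin cycle enzymes. Counting aligned panel reads alone they were 0.591% and 0.0221% for histones, 0.0181% and 0.00115% for cell cycle proteins, 0.597% and 0.0308% for ribosomal proteins, 0.0240% and 3.46% for C4 cycle enzymes, 0.0224% and 0.697% for Calvin cycle enzymes, 0.838% and 0.131% for tubulins and actins, 0.379% and 0.119% for heat shock proteins and 0.755% and 0.275% for reference genes.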

Other observations

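Proteins outside the fixed lists also differed between the libraries. Metallothionein, a small metal-binding protein, had 20 reads in the base library and 22732 in the tip library, 1150-fold higher in the tip library (744 to 1882), with a log2 ratio of 7.03 for distinct sequences against 10.17. Sucrose synthase, counted by panel windows, was 104-fold higher in the base library (88.9 to 121), and its 3 regions were all at least 4-fold higher there. Its log2 ratio went from -6.70 to -3.69 with distinct sequences counted once. The window count was 17397 reads in the base library, while its region on chromosome 9 alone held 152003, at a log2 ratio of -9.82. The windows miss many reads of that region, so the 104-fold may not hold for the whole family. The translation factors elongation factor 2 and eIF4A were higher in the base library, at log2 ratios of -3.81 and -2.48, and eIF4A did not reach 4-fold relative to the median region. With distinct sequences counted once these were -1.73 and -0.93. Leaf ferredoxin, which carries electrons from photosystem I, was 11.8-fold higher in the tip library (11.4 to 12.2). Cytosolic GAPDH of glycolysis had a log2 ratio of -0.75, which turned to 0.23 relative to the median region, beside 5.02 for the chloroplast subunit A. The mitochondrion-encoded Cox1 had 161 reads in the base library and 52 in the tip library.

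Within histone H3, the form made during DNA replication and the replacement form, told apart by 35 windows each, differed in their ratios. Histone H3.1 had 14489 reads in the base library and 95 in the tip library, and histone H3.3 had 4513 and 1327. The ratio of H3.1 to H3.3 reads was 3.21 in the base library and 0.0716 in the tip library (0.0575 to 0.0882). Of 72 measured families with regions, 10 had regions at least 4-fold higher in each direction. A cytosolic HSP70 region on chromosome 1 from 41229550 to 41231322 held 1819 reads in the base library and 8967 in the tip library, while the family had a log2 ratio of -1.70.

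The tests in the following paragraphs were chosen after the results they bear on were seen. Only for the 36-base tip reads alone was the deciding bound set before that test was run.

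A first pattern is the lower level of growth and translation transcripts in the tip library. If a few abundant transcripts had only taken reads from the rest, ribosomal proteins would lie at the median region, but they lay at -3.51 relative to it. If the 35-base reads had made the pattern, it would vanish with 36-base tip reads alone, where the ribosomal median was -3.73. Fewer dividing cells in the tip segment stay open: histone H3.1 fell more than the replacement form H3.3, by a log2 difference of -5.49 (-5.79 to -5.18), but H2A fell no more than its replacement form H2A.Z, with a difference of 0.0347 (-0.16 to 0.23). These histones belong to the pattern and had been seen before the test, which says nothing about translation transcripts, and each position has 1 library.

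A second pattern is that Rubisco large subunit had far more reads than other plastid-encoded proteins in both libraries, 448465 against 11460 for PsbA in the tip library and 35420 against 675 in the base library. All 6 plastid-encoded proteins had higher levels in the tip library, with a median log2 ratio of 3.89, or 4.87 relative to the median region, where AtpH passed 4-fold by going from 1.83 to 2.81. With distinct sequences counted once the median of the 6 was 2.79. Reads per found window of Rubisco large subunit were 29.9 times those of PsbA in the tip library and 40.2 times in the base library. Missed windows of PsbA cannot account for the gap, since 339 of its 343 windows were found. In the tip library a few strongly amplified sequences cannot either, since the median reads per window differed by 30.4 times (24.5 to 37.5). Selection on poly(A) and copies of plastid DNA in the nucleus stay open as untested explanations, and no biological explanation was tested.

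Another pattern lies within the tip library, where ribosomal proteins were rarer among 35-base than among 36-base reads for 15 of 15 proteins, with a median log2 ratio of -1.19 against -0.07 for 55 other proteins with at least 100 tip reads, of which some fell as far, such as nonspecific lipid-transfer protein (-1.16) and protochlorophyllide reductase (-1.11). Counting error is excluded by the summed reads, at -1.01 (-1.06 to -0.96). A different share of aligned reads as the whole cause would move all proteins alike, but ribosomal and C4 cycle medians differed by -1.36. Base-like tissue behind the 36-base reads, as the whole cause, would raise tubulins as much, but their log2 ratio was -0.0164 (-0.08 to 0.04); a part stays open, since 10 of 13 non-ribosomal proteins with at least 100 tip reads and at least 4-fold higher in the base library were lower at 35 bases (median -0.35, from -0.70 for histone H4 to 0.79 for phenylalanine ammonia-lyase). The reads of different length may come from separate preparations or runs, which the labels do not say, and no biological explanation was tested.

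The difference between reads of 35 and 36 bases shows a spread within the tip library. Among 54 proteins with at least 1000 tip reads its SD was 0.53 on the log2 scale, and it was largest for RPL15, at -1.50. Over 21641 regions the SD was 0.73, and 277 (1.28%) differed at least 4-fold. This spread holds no variation between libraries or plants, so it sets no upper limit on the error of a tip over base ratio.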
